A study of Mus musculus with 127 samples.

How the data were processed

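Single cell RNA sequencing was done on bone marrow cells of wild-type C57BL/6 mice. Per the labels' protocols, marrow was crushed from the hindlimbs, enriched with beads for CD117 (the Kit receptor), stained and sorted. Cells were captured and lysed on the Fluidigm C1 system, cDNA was made with the SMARTer kit, and libraries were made with Nextera XT. Per the labels, libraries of 96 cells were read as 150 bp paired-end reads. Each deposited sample was 1 cell, and the labels placed 46 cells in a gate called Ly6g high, 41 in a gate called Ly6g low and 40 in a gate called CD11b+. The labels named no animal, culture or donor.

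The authors deposited 1 table of 23946 genes by 127 cells as log2(TPM + 1), where TPM is a share of transcripts scaled to the same total in each cell. This unit was read from the values, because 2 to the power of each value, minus 1, summed to between 999633 and 1005383 TPM in every cell. Per the submitters' processing notes, Bowtie2, RSEM and the genome build mm9 were used. Their versions and the gene annotation were not given in the sources used here. A second deposited file gave each cell 1 of 11 class names, assigned by a method not given in the sources used here. The number of columns left without a sample was 0. The reference available was of another build, so no coordinates are given.

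The deposited log2 values were turned back to TPM. For each gate the mean TPM over all its cells was taken, and 2 gates were compared as the log2 ratio of the means after adding 1 TPM to each. Such a ratio understates differences of genes near 1 TPM. A gene was measured in a pair of gates if it stood at 1 TPM or more in at least 25% of the cells of either gate. Detection in a cell meant 1 TPM or more. Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

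Because no animal was named, each gate was treated as 1 sample. No test between gates was possible, no p-value was computed, and differences have no replicate check. SDs describe the spread over the cells of a gate. Gate means often rest on few cells: for 66 of the 87 genes taken for the text, the mean of at least 1 gate moved by over 1.5 times without its highest cell. The numbers in the cell names pair nothing across gates. Ly6g low cells were numbered 1 to 43 and Ly6g high cells 44 to 96. CD11b+ cells were numbered 1 to 48 and their names carry another run label, so that gate and its run cannot be told apart. The cell names end in codes read here as capture positions, and 18 of them occur in both Ly6g gates, which places these gates on separate plates. Gate and plate can therefore not be told apart in any of the 3 pairs.

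There were 24 gene lists, fixed before the data were examined, for granule types, blood cell types, cell cycle phases, metabolism and handling, and a further list of sex-linked genes. The median log2 ratio of each list with at least 3 measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart at or under the 2.5th or at or over the 97.5th percentile. This describes these libraries and is not a test.

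The rule for named genes was also fixed beforehand. The gate genes Ly6g, Itgam and Kit and 11 fixed genes (Gfi1, Irf8, Cebpe, Cebpa, Spi1, Klf4, Csf1r, Elane, Mpo, Camp and Ltf) were always named. For Ly6g high against Ly6g low the 12 highest and 12 lowest log2 ratios were named, and for the other pairs 6 each way. These came from measured genes with a mean of 10 TPM or more in either gate, a log2 ratio of size 1 or more, and a difference of mean log2(TPM + 1) of size 1 or more with the same sign. Gate genes, predicted loci, ribosomal protein, microRNA, small nucleolar and mitochondrial genes were left out. From lists that stood apart, members with the most extreme ratios in the direction of the median were named, and from other lists at most 3. Within the range the rule allowed, how many list members to name was set after the values were seen, at up to 3 in the first pair and 2 in the others. Some genes that the rule named are not reported here.

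TPM keeps no read depth, so depth was described by the number of genes detected per cell. No 2 columns were identical, and the highest correlation between any 2 cells was 0.884. All deposited cells were used and no doublet caller was run. The cells were not clustered, since the deposited classes were used. Alternatives covered the pseudocount, the filter, the kind of mean, rescaling, removal of granule genes, the cells with the fewest genes, and odd-numbered or even-numbered cells. Further alternatives were chosen after the data were seen: Myelo classes only, Myelo-2 cells only, cells with 1500 to 3000 genes, and detection at 100 TPM.

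The steps were tested on simulated data made from Ly6g low cells drawn at random for both gates of the pair Ly6g high and Ly6g low. With all 23946 genes, planted log2 changes of 1, 2 and 3 were recovered with medians of 0.86, 1.99 and 2.91, in the right direction for 86.6%, 100% and 100% of the 67, 67 and 66 genes changed. Over 4586 genes, 18 of 400 unchanged lists of 15 genes stood apart, and 99 of 100 lists shifted by a log2 of 1 did. These lists were genes drawn at random, so this checks only the ranking. It gives no rate of false calls for lists whose members vary together over cells. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.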

Results

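The transcriptomes of 127 single cells from wild-type mouse bone marrow were measured in 3 sorted gates of a population the labels call GMP-P, with 46 Ly6g high, 41 Ly6g low and 40 CD11b+ cells. Ly6g is a surface protein of granulocytes, and CD11b, encoded by Itgam, is an integrin of myeloid cells. The series concerns the cell states passed during granulocyte specification and commitment. The comparisons here ask how the gates differ in those states. Each gate was 1 sample without a named animal, so all differences between gates below lack a replicate check.

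The median number of genes detected per cell was 1695 in Ly6g high (range 966 to 4679), 2521 in Ly6g low (1159 to 5058) and 2464.5 in CD11b+ cells (821 to 5173). Genes of the 3 granule and mature neutrophil lists took a median of 59.6%, 55.7% and 29.3% of each cell's TPM. Of 23946 genes, 13508 were above 0 in at least 1 cell. Y-linked genes were detected in 22 of 46, 21 of 41 and 25 of 40 cells. Xist, expressed from the inactive X chromosome of females, was detected in 0 cells of each gate, with upper bounds of 7.71%, 8.60% and 8.81%.

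The genes of the sorting markers were compared with the gate names. Mean Ly6g was 936 TPM in Ly6g high, 353 TPM in Ly6g low and 171 TPM in CD11b+ cells, with detection in 78.3%, 68.3% and 20% of the cells, and 50.95% of the CD11b+ sum came from 1 cell (86.2 TPM without it). The medians were 180, 1.96 and 0 TPM, so part of the Ly6g low detections lay near the minimum of 1 TPM. Itgam was at 228, 112 and 66.9 TPM and was detected in 89.1%, 90.2% and 67.5% of the cells. Kit was at 2.56, 19.9 and 63.5 TPM.

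The authors' deposited classes were distributed unequally over the gates. Myelo-2 was the most frequent class in each gate, with 27 of 46 Ly6g high cells (58.7%, 95% interval 43.2 to 73), 31 of 41 Ly6g low cells (75.6%, 59.7 to 87.6) and 14 of 40 CD11b+ cells (35%, 20.6 to 51.7). Myelo-4 held 13 Ly6g high cells (28.3%, 16 to 43.5), 0 Ly6g low cells (upper bound 8.60%) and 3 CD11b+ cells (7.5%, 1.57 to 20.4). Myelo-1 held 0, 4 and 1 cells, and Myelo-3 held 3, 2 and 4. The 4 Myelo classes together made up 93.5% of Ly6g high (82.1 to 98.6), 90.2% of Ly6g low (76.9 to 97.3) and 55% of CD11b+ cells (38.5 to 70.7). The Gran classes held 0, 2 and 8 cells, HSCP-2 held 2, 0 and 5 and Mono held 1, 1 and 3. The single MDP cell was in Ly6g low, and the single Eryth and Multi-Lin cells were in CD11b+.

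**Figure D1:**
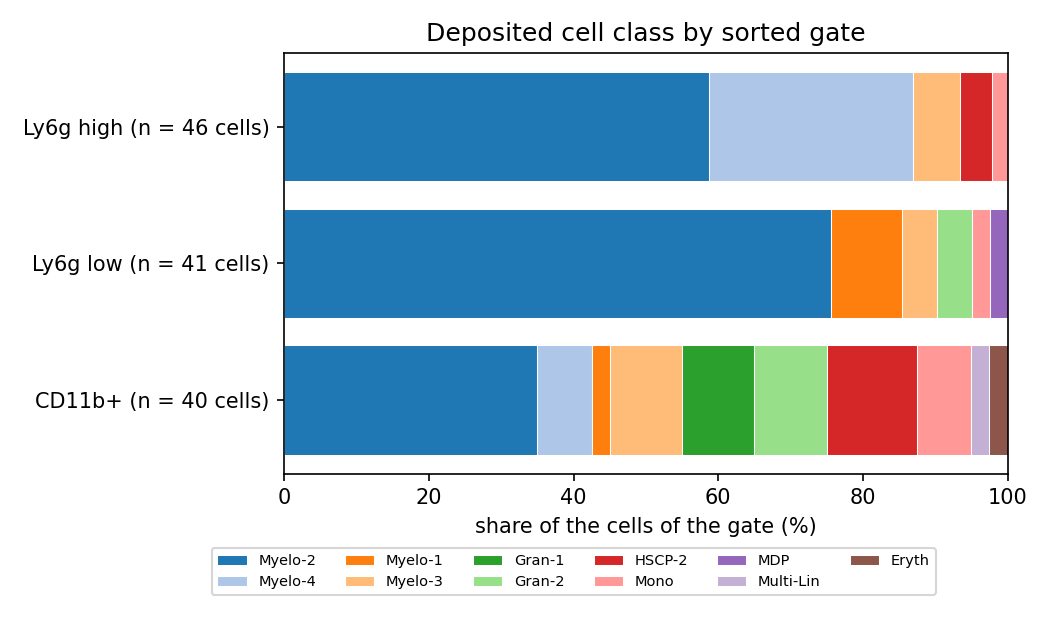
Share of the cells of each gate (%, horizontal axis from 0 to 100) in each class deposited by the authors, for 46 Ly6g high, 41 Ly6g low and 40 CD11b+ cells. Myelo-4 makes up 28.3% of Ly6g high and 0% of Ly6g low cells, and 55% of CD11b+ cells are in a Myelo class.

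Ly6g high cells carried more transcript of mature neutrophil genes than Ly6g low cells, and less of primary granule, DNA replication and endoplasmic reticulum genes. Mmp9, the gelatinase of late granules, had a mean of 333 TPM in Ly6g high and 3.42 TPM in Ly6g low cells and was detected in 69.6% and 7.32% of them, with a mean log2(TPM + 1) of 4.92 ± 3.99 and 0.41 ± 1.18 (SD over cells). Without the 1 cell that gave 90.4% of the Ly6g low sum, the Ly6g low mean was 0.338 TPM. Mmp8, a collagenase of neutrophil granules, stood at 644 and 0.917 TPM (log2 ratio 8.39, but -0.92 in Myelo-2 cells alone), and Retnlg at 3298 and 97.6 TPM (263 and 127 TPM in Myelo-2 cells alone, 11124 TPM in the Ly6g high Myelo-4 cells). Lig1, a DNA ligase of replication, was at 6.45 and 80.5 TPM, and the helicase subunit Mcm3 at 13.5 and 109 TPM, where 1 cell gave 95.5% of the Ly6g high sum. Elane, the neutrophil elastase of primary granules, was at 98.2 and 4739 TPM. It was at 1 TPM or more in like shares of the cells (36.96% and 39.02%), with medians of 0.51 and 0.75 TPM. The likeness holds near this low minimum, since at 5 TPM Elane with Ltf was found in 0% of Ly6g high and 22% of Ly6g low cells. Of the Ly6g high sum of Elane, 99.05% came from 1 cell of class Mono (cell 77), and the mean without it was 0.959 TPM. In Ly6g low cells 24.1% of the sum came from 1 cell of class Gran-2 (cell 6), and the Myelo-2 cells had a mean of 711 TPM. The primary granule list median below was -4.93 without cell 77 and -3.06 without cell 6.

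Over the 3983 measured genes the median log2 ratio of Ly6g high over Ly6g low was -0.29, and list medians are to be read against this shift. The late neutrophil list had a median of 1.15 (matched random lists -0.23, percentile 100), with all 11 measured members above 0 and 7 at least 2-fold higher. Its members included Fpr2, a formyl peptide receptor (299 against 67.6 TPM). The primary granule list had a median of -3.41 (random -0.27, percentile 0), with 7 of 8 members at least 2-fold lower. They included Cst7 (2.51 against 109 TPM) and Nkg7 (28.7 against 734 TPM), for which 1 cell gave 98.98% and 88.2% of the Ly6g high sum. The S phase list had a median of -1.70 (random -0.27, percentile 0), with 17 of 19 members at least 2-fold lower. Pola1, a DNA polymerase subunit, was at 0.683 and 24 TPM. The endoplasmic reticulum list had a median of -1.06 (random -0.27, percentile 0.02), with 13 of 19 members at least 2-fold lower. Its members Dnajc3 (2.98 against 17.7 TPM), P4hb (95.2 against 303 TPM) and Pdia3 (84 against 231 TPM) are protein folding factors.

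The monocyte list, with 4 measured members of 18, had a median of 1.10 (percentile 99.9), led by Slfn1 (162 against 3.95 TPM), the galectin gene Lgals3 (378 against 114 TPM) and Psap (15.9 against 11.2 TPM), while Ly6c2 was lower (1578 against 2361 TPM). For Slfn1, 1 cell gave 90.8% of the Ly6g low sum, and without the highest cell of each gate Psap was at 9.99 and 6.13 TPM. The adhesion list had a median of 0.30 (percentile 99.1), with Ceacam10 at 176 and 49.9 TPM. Other lists did not stand apart. Their medians were 0.06 for specific granules, -0.24 for granulocyte regulators, -0.34 for mitosis, -0.36 for ribosome assembly, 0.05 for the NADPH oxidase, -0.42 for immediate early genes, -0.02 for glycolysis and -0.44 for the respiratory chain. The specific granule gene Camp was at 55886 and 55818 TPM, Ltf at 10091 and 7241 TPM, and Fcnb at 973 and 2902 TPM. The mitosis genes Aurka and Cdc20 were at 30.04 and 22.99 TPM in Ly6g high and at 96.3 and 71.7 TPM in Ly6g low cells. The progenitor, dendritic, interferon, erythroid, megakaryocyte, basophil and mast cell, eosinophil, B cell, T and NK cell and macrophage lists had at most 2 measured members here, as they did in the other pairs except for the progenitor list.

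Among transcription factors, Cebpe was at 106 TPM in Ly6g high (mean log2(TPM + 1) 4.85 ± 2.83, SD over 46 cells) and 82.3 TPM in Ly6g low cells (5.15 ± 2.19, 41 cells). Spi1 was at 64.9 and 34 TPM and Cebpa at 1.27 and 8.92 TPM, with a Ly6g high mean of 0.118 TPM for Cebpa without 1 cell. Gfi1 was detected in 10.9% of Ly6g high and 17.1% of Ly6g low cells, with means of 21.3 and 6.42 TPM, and 72.1% of the Ly6g high sum came from 1 cell. Irf8 and Csf1r, of monocyte development, were each detected in 1 cell of each of the 2 gates, and Klf4 in 0 of the Ly6g high and 4.88% of the Ly6g low cells. Mpo, myeloperoxidase, was at 271 and 2072 TPM, of which 99.8% of the Ly6g high sum came from the same Mono cell. Further genes higher in Ly6g high cells were Sh3glb1, Rinl, Ppm1a, Scrg1, Arid4b, Inhba and Fcho2, with log2 ratios from 2.67 for Fcho2 to 4.36 for Sh3glb1. A single cell gave 51.7% of the Ly6g high sum of Sh3glb1, 56.4% for Scrg1 and 88.9% of the Ly6g low sum of Fcho2. Further genes lower in Ly6g high cells were Tmem129, Txndc12, Haus1, Fam134a, Hint3, Gsto1, Mrps7, Mt1 and St3gal4, with log2 ratios from -5.82 for Tmem129 to -4.51 for St3gal4. Of the Ly6g low sum, 1 cell gave 56% for Hint3, 53.1% for St3gal4 and 42% for Gsto1, and of the Ly6g high sum 1 cell gave 99.3% for Tmem129. Of the genes meeting the size rule, 48 were higher and 682 lower in Ly6g high cells, beside its lower number of genes detected.

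In cells with 1500 to 3000 genes, a setting chosen after the data were seen, the primary granule median was -0.56 and no longer stood apart, Mpo turned to 0.19 and Cst7 to 0.031. The endoplasmic reticulum median was 0.0027 in odd-numbered and -1.77 in even-numbered cells, and the list stood apart in 11 of 14 alternatives, not in odd-numbered cells, in the Myelo classes only or with the 10% trimmed mean. The monocyte median was 0.25 and no longer stood apart without the cells with the fewest genes. The monocyte list stood apart in 10 of 13 alternatives, also not with no filter on low values or with 1500 to 3000 genes. The adhesion median turned to -0.13 with the mean of log2(TPM + 1), still above its random lists, and Scrg1 turned to -0.97 in odd-numbered cells. The adhesion list stood apart in 11 of 14 alternatives, not without the cells with the fewest genes, in odd-numbered cells or with 1500 to 3000 genes.

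**Figure D2:**
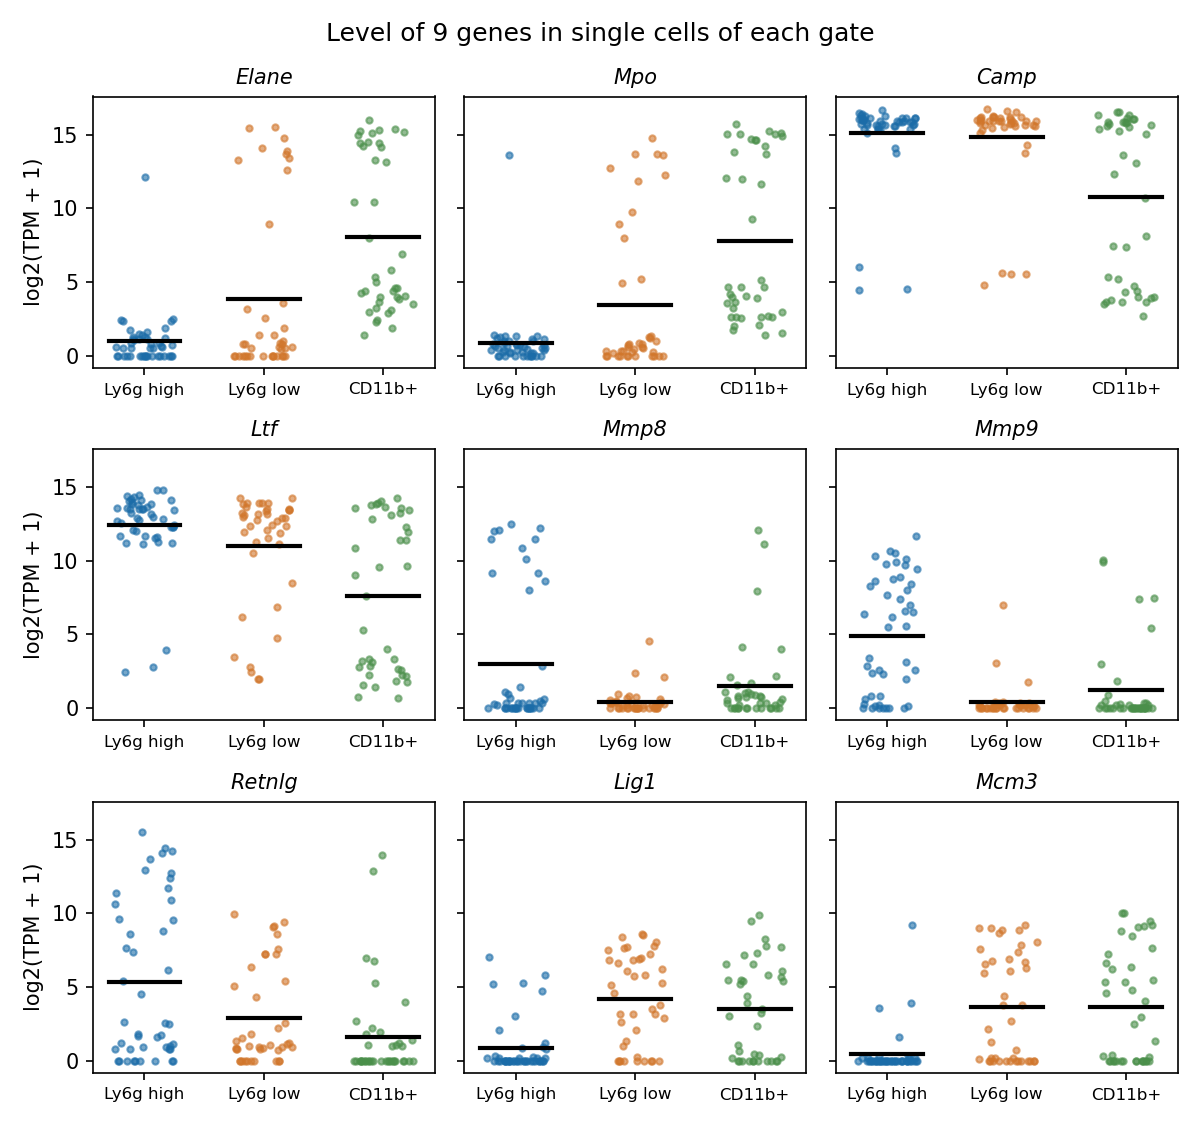
Level of 9 genes in each cell as log2(TPM + 1) (vertical axis), by gate (horizontal axis, 46 Ly6g high, 41 Ly6g low and 40 CD11b+ cells), where each point is 1 cell, spread sideways at random, and bars are means over cells. Elane is above 10 on this scale in 1 Ly6g high cell, and Mmp9 is detected in 69.6% of Ly6g high and 7.32% of Ly6g low cells.

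CD11b+ cells carried more transcript of primary granule, ribosome assembly and immediate early genes than Ly6g low cells, and less of specific granule, mitosis and NADPH oxidase genes. Mpo was at 9997 TPM in CD11b+ and 2072 TPM in Ly6g low cells, Elane at 10542 and 4739 TPM, and Ctsc, a protease that activates granule enzymes, at 30.5 and 5.42 TPM, where 1 cell gave 90.2% of the Ly6g low sum. Nop2 and Mybbp1a, nucleolar proteins, stood at 37.8 and 38.2 TPM in CD11b+ and at 0.427 and 2.97 TPM in Ly6g low cells. A single cell gave 98.4% of the Ly6g low sum of Nop2, and without 1 cell of each gate Mybbp1a was at 21.5 and 1.54 TPM. The transcription factor Klf6 was at 327 and 75.8 TPM, and the chaperone Hspa8 at 2631 and 630 TPM. Camp was at 30218 and 55818 TPM and Ltf at 4376 and 7241 TPM.

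Over 4774 measured genes the median log2 ratio of CD11b+ over Ly6g low was 0.48. The primary granule median was 1.39 (random lists 0.51, percentile 99.9), with 8 of 10 members at least 2-fold higher. The ribosome assembly median was 2.08 (random 0.53, percentile 100), with 16 of 16 at least 2-fold higher. The immediate early median was 1.70 (random 0.47, percentile 100), with 13 of 16 at least 2-fold higher. The specific granule median was -0.89 (random 0.50, percentile 0), with 5 of 15 members at least 2-fold lower, among them Itgb2l (79.6 against 261 TPM) and Orm1 (95.2 against 222 TPM). The mitosis median was -0.50 (random 0.53, percentile 0), with Cenpf at 3.84 and 23.2 TPM (68.1% of the CD11b+ sum from 1 cell) and Cdc20 at 22.1 and 71.7 TPM. The NADPH oxidase median was -0.52 (percentile 0.28), with Cyba at 995 and 1467 TPM and Cybb at 599 and 875 TPM. The late neutrophil median was 1.40 (percentile 99.8), led by Trem1 (36.4 against 5.25 TPM) and Retnlg (590 against 97.6 TPM). It was 0.095 without 1 CD11b+ cell of class Myelo-3 (cell 13), and 1 cell gave 67.1% of the CD11b+ sum of Retnlg.

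Medians of the other lists lay among their random lists, at 1.15 for monocyte, 1.62 for progenitor, 0.49 for granulocyte regulator, 0.49 for S phase, 0.51 for endoplasmic reticulum, 0.36 for adhesion, 0.26 for glycolysis and 0.45 for respiratory chain genes. Gfi1 was at 11 TPM in CD11b+ cells, Irf8 at 7.63, Cebpe at 68.2, Cebpa at 7.25, Spi1 at 14, Klf4 at 32.6 and Csf1r at 5.06 TPM, with 74.65% of the sum of Klf4, 72.01% of Cebpa, 70.01% of Irf8, 67.6% of Csf1r, 56.99% of Gfi1 and 53.3% of Spi1 from 1 cell. The genes with the highest ratios were Oxa1l, Mmp8, Zer1, Pdrg1, Safb and Tmem242, with log2 ratios from 4.99 for Tmem242 to 7.14 for Oxa1l. A single cell gave 93.7% of the CD11b+ sum of Oxa1l, 88.4% for Tmem242, 78.85% for Zer1, 73.1% for Safb and 63% for Mmp8, and 37.3% for Pdrg1. Acot8, Ggh, Mlst8, Trim59, Marcksl1 and Ndufs5 were lower in CD11b+ cells, with log2 ratios from -3.74 for Acot8 to -3.19 for Ndufs5.

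Within the Myelo classes, settings chosen after the data were seen, most of these differences were lost or turned, while the immediate early list still stood apart with the 4 Myelo classes and the late neutrophil median was 2.28 there. With the 22 CD11b+ and 37 Ly6g low cells of the 4 Myelo classes the primary granule median was -1.34, below its random lists, with Elane, Mpo, Ctsc and Kit at log2 ratios of -1.31, -1.48, -0.63 and -0.28. The ribosome assembly median was -0.64 there, and Mybbp1a, Oxa1l and Tmem242 turned to -0.36, -0.17 and -0.37. Among the 14 CD11b+ and 31 Ly6g low Myelo-2 cells the medians were -0.11 for primary granule, -0.44 for ribosome assembly, 0.097 for immediate early, -0.13 for specific granule, 0.088 for mitosis and 0.024 for NADPH oxidase genes, and none of these stood apart. Elane, Ctsc, Kit, Mmp8 and Tmem242 were at log2 ratios of -1.60, -2.92, -3.12, -0.50 and -0.044 in Myelo-2 cells. The late neutrophil list stood apart on the same side in 6 of 13 alternatives, and its median was -0.43 with the mean of log2(TPM + 1). In cells with 1500 to 3000 genes the primary granule median was 6.14.

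Among the list medians, CD11b+ cells differed from Ly6g high cells most in primary granule genes, except in odd-numbered cells (4.01, against 4.28 for progenitor genes). Elane was at 10542 TPM in CD11b+ and 98.2 TPM in Ly6g high cells, and Cst7 at 325 and 2.51 TPM. The replication genes Lig1 and Mcm4 were at 83.7 and 274 TPM in CD11b+ and at 6.45 and 24.7 TPM in Ly6g high cells. Mmp9 was at 61.1 and 333 TPM, Retnlg at 590 and 3298 TPM, and Mmp8 at 174 and 644 TPM. Cd69, an early activation antigen, was at 401 and 0.033 TPM and the chemokine Ccl3 at 305 and 1.88 TPM, with 51% of the CD11b+ sum of Ccl3 and 39.8% of Cd69 from 1 cell, and a CD11b+ mean of 35.2 TPM for Mmp9 without 1 cell.

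Over 4447 measured genes the median log2 ratio of CD11b+ over Ly6g high was 0.83. The primary granule median was 5.12 (random 0.84, percentile 100), with 9 of 10 members at least 2-fold higher. It was 4.96 without CD11b+ cell 9 of class Gran-1 and 6.15 without the Ly6g high Mono cell (cell 77). The S phase median was 1.86 (random 0.85, percentile 99.8), with 21 of 23 at least 2-fold higher. The ribosome assembly median was 2.22 (percentile 99.9), and was 1.99 without CD11b+ cell 29 and 3.81 without cell 77. Fbl was at 47.3 and 1.04 TPM (0.599 without 1 Ly6g high cell) and Nop2 at 37.8 and 1.35 TPM (0.003 without 1 Ly6g high cell). The endoplasmic reticulum median was 1.72 (percentile 99.8), with Dnajb9 at 138 and 0.202 TPM and Pdia4 at 85.1 and 1.90 TPM. For Dnajb9, 1 cell gave 55.8% of the CD11b+ sum, and for Pdia4 1 cell gave 97.8% of the Ly6g high sum. The immediate early median was 2.16 (percentile 100), with Hspa1a at 19.3 and 0.485 TPM (the Ly6g high sum from 1 cell) and Dusp1 at 573 and 56.2 TPM. The progenitor median was 3.23 (percentile 98.6) over 3 members including Kit and Myb. Myb was at 325 and 33.8 TPM, and 75.3% of the CD11b+ sum came from 1 cell. Without 1 CD11b+ cell of class HSCP-2 (cell 21) the progenitor median was 1.26, and the list stood apart in 5 of 10 alternatives.

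On the lower side, the specific granule median was -0.91 (random 0.84, percentile 0), with Itgb2l at 79.6 and 463 TPM, and the late neutrophil median was -0.60 (percentile 0.04). Medians were -0.15 for mitosis (percentile 0.04), with Cenpa at 29.1 and 117 TPM and Cenpf at 3.84 and 16.6 TPM, and -0.49 for the NADPH oxidase (percentile 0.67), with Cyba at 995 and 1678 TPM and Cybb at 599 and 913 TPM. The adhesion median of 0.02 lay below its random lists at 0.84 (percentile 1.95), although Itgal (48.3 against 10.4 TPM, with 82.7% of the CD11b+ sum from 1 cell) and Itga4 (15.1 against 2.85 TPM) were higher in CD11b+ cells. The adhesion list stood apart on this side in only 8 of 14 alternatives. Monocyte, granulocyte regulator, glycolysis and respiratory chain medians of 0.95, 0.40, 0.48 and 0.72 lay among their random lists. Zer1 was also among the highest, with a log2 ratio of 6.45. Scrg1, Acpp, Slfn2, Ndufs5 and Ppm1a were among the lowest, with log2 ratios from -4.32 for Scrg1 to -3.27 for Ppm1a.

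Among Myelo-2 cells the ribosome assembly and NADPH oxidase medians turned to -0.18 and 0.16, the endoplasmic reticulum, immediate early and specific granule medians of 0.45, 0.82 and -0.098 no longer stood apart, and Kit, Myb, Fbl, Itga4 and Mmp8 turned to log2 ratios of -1.10, -0.15, -0.53, -1.99 and 0.42. The mitosis median turned to 0.38 in even-numbered cells and to 0.011 without 1 Ly6g high cell (cell 62), and the adhesion median lay between -0.22 and 0.15 when each cell was left out in turn.

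**Figure D3:**
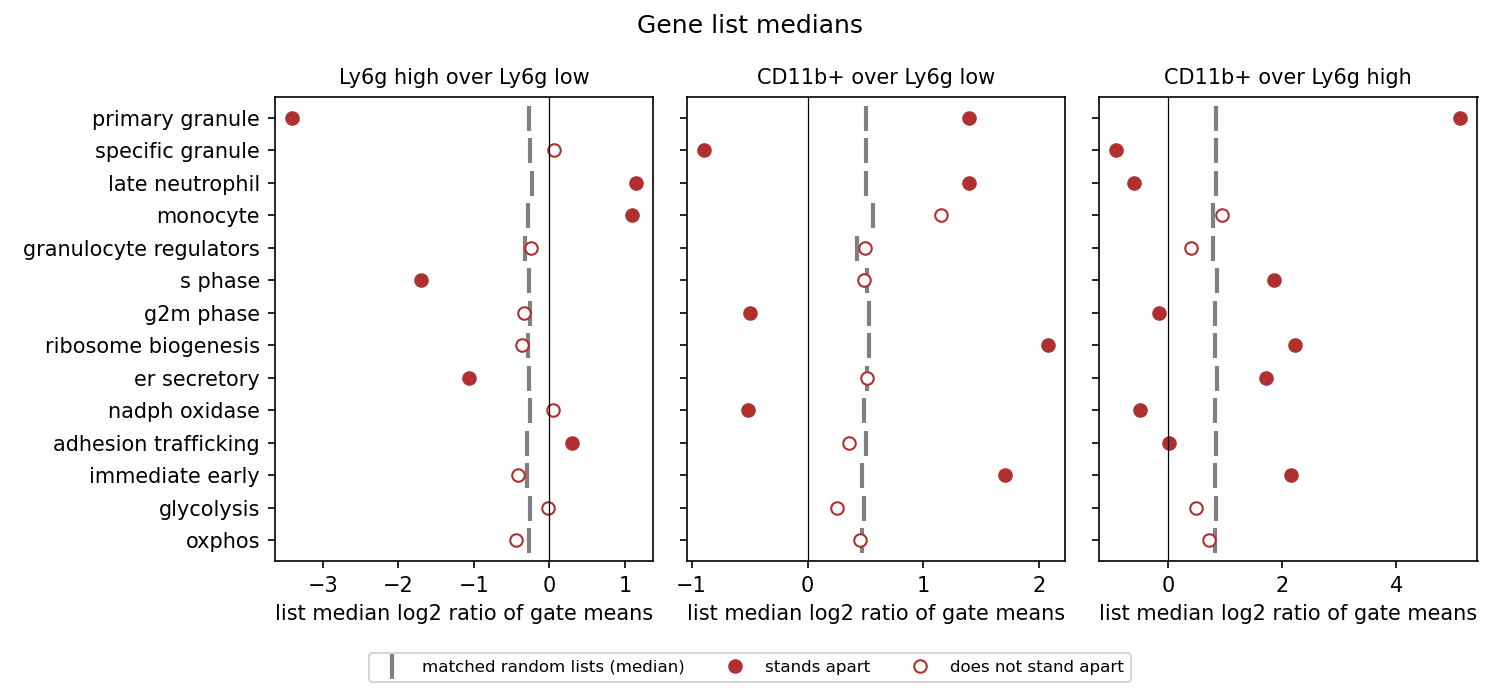
Median log2 ratio of gate means (horizontal axis) of 14 gene lists (vertical axis) for the 3 pairs of gates, with filled circles for lists that stood apart from matched random lists, open circles for those that did not, and grey bars for the median of the random lists. The primary granule median is -3.41, 1.39 and 5.12 in the 3 pairs.

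Joint detection of pairs of genes in single cells was counted next. Gfi1 and Irf8 were detected together in 0 of 46 Ly6g high, 0 of 41 Ly6g low and 1 of 40 CD11b+ cells (upper bounds 7.71%, 8.60% and 13.2%), and at 5 TPM in 0 of each. Gfi1 and Cebpe were found together in 5, 7 and 6 cells (0% of Ly6g low and CD11b+ cells at 100 TPM), and Cebpe and Irf8 in 0, 0 and 1. Irf8 was detected in only 1, 1 and 4 cells, so low joint counts with it follow from its rarity. They do not show that Irf8 and the other factors exclude each other. At 1 TPM Camp was detected in 100% of the cells of each gate, Ltf in 100%, 100% and 95%, and Elane in 100% of the CD11b+ cells, so that joint shares with these genes there largely repeat the share of the other gene. Camp was detected even in the 1 cell classed Eryth, at 19.1 TPM, where Elane stood at 11.3 TPM. Irf8 was found with Elane in 1, 1 and 4 cells, as was Csf1r. Mki67, a marker of cycling cells, was found with Camp in 56.5% (41.1 to 71.1), 80.5% (65.1 to 91.2) and 72.5% (56.1 to 85.4) of the cells, and Kit with Camp in 13%, 22% and 47.5%. Shares were 19.6%, 36.6% and 100% for Mpo with Camp, 37%, 39% and 95% for Elane with Ltf, and 2.17%, 7.32% and 12.5% for Cd34 with Ltf. At 100 TPM, Mpo and Camp were found together in 0%, 14.6% and 17.5% of the cells, Elane and Ltf in 0%, 9.76% and 15% and Cd34 and Ltf in 0% of each gate. Kit and Camp were then found together in 0%, 7.32% and 10%, and Mki67 and Camp in 21.7%, 26.8% and 15%.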

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

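Settings limited to Myelo classes, Myelo-2 cells or 1500 to 3000 genes, and detection at 100 TPM, were chosen after the data were seen. No paired analysis was possible because each gate is 1 sample and no result comes from a test. In each alternative that gave a value, 5 list differences stood apart on the same side. These were late neutrophil (13 alternatives) and S phase (14) in Ly6g high over low, and primary granule (13), S phase (14) and late neutrophil (13) in CD11b+ over Ly6g high, with ranges of 0.46 to 1.44, -2.95 to -1.01, 4.01 to 9.70, 1.03 to 3.80 and -1.70 to -0.16. Primary granule genes in Ly6g high over low stood apart on the same side in 11 of 12, and immediate early genes in CD11b+ over Ly6g low in 13 of 14. Over all lists, 450 values moved by less than 1.5-fold, 119 moved more and 24 that stood apart changed sign. For the genes named, these numbers were 1037, 769 and 23. Of the shares and gene numbers, 243 stayed within their interval or spread and 90 did not. Removing granule lists leaves no primary granule, specific granule or late neutrophil value. TPM keeps no depth, so effects of depth could not be separated beyond genes per cell. The cause of the changes below was not tested, except that settings with fewer cells or classes change which cells enter.

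Given below are lists that stood apart where their median moved by 1.5-fold or more or changed sign, genes meeting the size rule only where their ratio changed sign, and shares of cells with 2 genes or in a class that left their interval. Other changes are in the counts above. With a pseudocount of 10, CD11b+ over Ly6g high gave progenitor 2.55. With no filter, Ly6g high over low gave monocyte 0.47. CD11b+ over Ly6g high had progenitor 1.11. With the filter at 50%, CD11b+ over Ly6g high gave adhesion -0.25. With the mean of log2(TPM + 1), Ly6g high over low gave primary granule -2.63, late neutrophil 0.46, S phase -2.67, endoplasmic reticulum -1.84 and adhesion -0.13. The same setting put CD11b+ over Ly6g low at primary granule 2.40, specific granule -3.13, late neutrophil -0.43, ribosome assembly 1.06, NADPH oxidase -1.87 and immediate early 0.78. Values for CD11b+ over Ly6g high were specific granule -2.68, late neutrophil -1.70, progenitor 2.16, mitosis 0.20 and adhesion -0.47. With a 10% trimmed mean, Ly6g high over low gave primary granule -8.17, monocyte 1.72 and S phase -2.95. CD11b+ over Ly6g low stood at primary granule 2.11, late neutrophil -0.40 and ribosome assembly 2.67. Such values for CD11b+ over Ly6g high were primary granule 9.70, progenitor 1.79, S phase 3.80, ribosome assembly 3.47, endoplasmic reticulum 2.60 and adhesion -0.45. With the median of all genes set to 0, CD11b+ over Ly6g high gave primary granule 4.29, specific granule -1.74, late neutrophil -1.43, progenitor 2.40, S phase 1.03, mitosis -0.98, ribosome assembly 1.39, endoplasmic reticulum 0.90, NADPH oxidase -1.31, adhesion -0.80 and immediate early 1.34. With granule lists taken out, CD11b+ over Ly6g high gave endoplasmic reticulum 1.08, adhesion -0.42 and immediate early 1.33. Without the fifth of cells with the fewest genes, Ly6g high over low gave monocyte 0.25. As to CD11b+ over Ly6g low, it gave late neutrophil -0.23. There, CD11b+ over Ly6g high gave progenitor 2.32. Without the fifth of cells with the fewest genes, the share of Myelo-3 in Ly6g low cells was 0%. In odd-numbered cells, Ly6g high over low gave primary granule -1.09, endoplasmic reticulum 0.0027 and Scrg1 -0.97. CD11b+ over Ly6g low had primary granule 2.44, late neutrophil 2.51, ribosome assembly 3.86 and immediate early 2.74. The same setting put CD11b+ over Ly6g high at primary granule 4.01, progenitor 4.28 and adhesion 0.65. In even-numbered cells, Ly6g high over low gave primary granule -5.74 and endoplasmic reticulum -1.77. Values for CD11b+ over Ly6g low were primary granule 0.73, late neutrophil -0.13, ribosome assembly 1.06, immediate early 0.91 and Ctsc -0.21. CD11b+ over Ly6g high stood at primary granule 6.13, late neutrophil -1.22, progenitor 1.04, S phase 2.88, mitosis 0.38, ribosome assembly 3.65 and adhesion -0.0222. In the Myelo classes, Ly6g high over low gave primary granule -7.81. Such values for CD11b+ over Ly6g low were primary granule -1.34, specific granule -0.24, late neutrophil 2.28, ribosome assembly -0.64, Ctsc -0.63, Elane -1.31, Kit -0.28, Mpo -1.48, Mybbp1a -0.36, Oxa1l -0.17 and Tmem242 -0.37. As to CD11b+ over Ly6g high, it gave primary granule 6.68, endoplasmic reticulum 0.42, immediate early 1.55 and Myb -0.23. In Myelo-2 cells, Ly6g high over low gave primary granule -6.49, S phase -1.01 and Mmp8 -0.92. There, CD11b+ over Ly6g low gave primary granule -0.11, specific granule -0.13, late neutrophil 0.26, mitosis 0.088, ribosome assembly -0.44, NADPH oxidase 0.0239, immediate early 0.10, Ctsc -2.92, Elane -1.60, Kit -3.12, Mmp8 -0.50 and Tmem242 -0.0435. CD11b+ over Ly6g high had specific granule -0.10, ribosome assembly -0.18, endoplasmic reticulum 0.45, NADPH oxidase 0.16, adhesion -0.51, immediate early 0.82, Fbl -0.53, Itga4 -1.99, Kit -1.10, Mmp8 0.42 and Myb -0.15. In cells with 1500 to 3000 genes, Ly6g high over low gave primary granule -0.56, Cst7 0.0307 and Mpo 0.19. The same setting put CD11b+ over Ly6g low at primary granule 6.14 and late neutrophil 0.15. Values for CD11b+ over Ly6g high were ribosome assembly 0.88, endoplasmic reticulum 0.96 and adhesion -0.0152. At 5 TPM, shares in Ly6g high cells were Mpo with Camp 2.17% and Elane with Ltf 0%. In Ly6g low cells they were Elane with Ltf 22%. In CD11b+ cells they were Gfi1 with Irf8 0%, Mpo with Camp 85% and Elane with Ltf 67.5%. At 10 TPM, shares in Ly6g high cells were Mpo with Camp 2.17%, Elane with Ltf 0% and Cd34 with Ltf 0%. In Ly6g low cells they were Elane with Ltf 17.1% and Cd34 with Ltf 0%. In CD11b+ cells they were Gfi1 with Irf8 0%, Mpo with Camp 65%, Elane with Ltf 37.5%, Gfi1 with Cebpe 5% and Cd34 with Ltf 2.5%. At 100 TPM, shares in Ly6g high cells were Mpo with Camp 0%, Elane with Ltf 0%, Kit with Camp 0%, Cd34 with Ltf 0% and Mki67 with Camp 21.7%. In Ly6g low cells they were Mpo with Camp 14.6%, Elane with Ltf 9.76%, Kit with Camp 7.32%, Gfi1 with Cebpe 0%, Cd34 with Ltf 0% and Mki67 with Camp 26.8%. In CD11b+ cells they were Gfi1 with Irf8 0%, Elane with Irf8 2.5%, Elane with Csf1r 2.5%, Mpo with Camp 17.5%, Elane with Ltf 15%, Kit with Camp 10%, Gfi1 with Cebpe 0%, Cebpe with Irf8 0%, Cd34 with Ltf 0% and Mki67 with Camp 15%.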

Other observations

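The test of a common ratio for granule transcripts was chosen after the result was seen, as were the settings with Myelo-2 cells only and with 1500 to 3000 genes. The bounds of the other tests were set before their results were seen, while their spread was chosen after the values themselves were seen. It is the 95% interval over 500 draws of the cells with replacement, together with the range when each cell was left out in turn, or the interval of a difference of shares. It covers sampling of cells only.

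Within the Myelo-2 class, the S phase median of Ly6g high over Ly6g low was -1.01 and the mitosis median 0.46, 0.95 below and 0.51 above their random lists. The difference between the lists was not tested. Lig1 was detected in 7 of 27 Ly6g high and 22 of 31 Ly6g low Myelo-2 cells, and the S phase gene Prim1 in 11 and 11. The mitosis gene Cenpa was detected in 20 and 15, and Mki67 in 21 and 24. In the 13 Ly6g high cells of class Myelo-4, 19 of 24 S phase genes and 21 of 24 mitosis genes were detected in 0 cells. The median of genes detected was 1409 in Myelo-4 and 2239.5 in Myelo-2 cells. Of the S phase and mitosis genes that were detected, Tyms was found in 10 cells and Mki67 and Slbp in 2 each, while Mmp9 was detected in 13. The 2 classes and these genes were chosen after their values were seen.

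Some single cells stood out, and are named after their values were seen. The only cell classed MDP, in Ly6g low (cell 40), carried the basophil and mast cell genes Prss34 (172424 TPM), Mcpt8 (43285 TPM) and Cpa3 (5258 TPM). It also carried the primary granule genes Mpo (6908 TPM) and Ctsg (3079 TPM), while Irf8, Csf1r and Flt3 were listed at 0. All 5 cells classed Mono carried Csf1r and primary granule transcripts, with a mean of 13732 TPM for Elane and 22517 TPM for Mpo. Their median of 4679 genes detected was the highest of the classes. Itgam was detected in 0 of the 7 HSCP-2 cells, 5 of which were in the CD11b+ gate and 2 in the Ly6g high gate. Egr1 lay between 2.44 and 8061 TPM in those 5 and was at 645 and 1518 TPM in those 2.

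Primary granule, S phase and endoplasmic reticulum genes were lower in Ly6g high than in Ly6g low cells, and gate and plate cannot be told apart. In Myelo-2 cells, primary granule genes stood at -6.427 relative to random lists (interval -7.76 to -0.60, narrowly beyond the bound of a 1.5-fold change). This value covers 6 measured members, without Mpo. Of the Ly6g low sum, 3 of 31 cells each gave 99.8% for Elane, 97.4% for Srgn, 93.4% for Prtn3 and 83.98% for Nkg7. The shares were lower for Ms4a3 (39.96%) and Serpinb1a (19.6%). Srgn and Prtn3 were detected in 8 of 31 Ly6g low and in 1 and 3 of 27 Ly6g high cells. Nkg7 was detected in 0 of 27 Ly6g high and 12 of 31 Ly6g low cells, Ms4a3 in 10 and 25, and Serpinb1a in 26 and 30. Elane was detected in 11 of 27 Ly6g high and 8 of 31 Ly6g low cells, with means of 1.02 and 711 TPM. Few cells carry most of the sum for Elane, Srgn, Prtn3 and Nkg7, although Nkg7 and Ms4a3 were detected in larger shares of the Ly6g low cells. The list value therefore cannot decide on a different mix of the deposited classes for primary granule genes. Such a mix also stays open for S phase (-0.9515, -1.87 to -0.41) and endoplasmic reticulum genes (-0.6102, -1.01 to -0.068). In cells with 1500 to 3000 genes S phase genes still stood at -1.3115 (-2.19 to -0.59), narrowly beyond the bound, while the median over all genes was 0.08. This window narrows the difference in genes detected without equalizing it, and it changes which classes enter. Fewer genes detected per cell is therefore not excluded for S phase genes. It also stays open for primary granule (-0.623, -2.30 to -0.11) and endoplasmic reticulum genes (-0.5911, -1.04 to 0.0037). The granule lists took like shares in the 2 gates (medians 59.6% and 55.7%), so their removal could move ratios only little. After it the S phase list median itself, not set against random lists, was -1.7752 (-2.67 to -1.07) over 20 members, beside -1.70 over 19 before. This outcome followed largely from the like shares, so the removal was no separate evidence. It is the like shares that argue against granule genes taking most of each cell's total for S phase genes. The shares bear on endoplasmic reticulum genes in the same way, where the list median was -0.796 (-1.36 to -0.32) after removal, beside -1.06 before. That interval reached past the bound of a 1.5-fold change, so the removal left these genes undecided. The same explanation was not tested for primary granule genes. A difference in stage between the gates may contribute as well, which was not tested further.

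Immediate early genes were higher in CD11b+ than in Ly6g low cells, with a median of 1.70. In Myelo-2 cells the median stood -0.0509 from its random lists, near 0 as a different mix of classes would give. The interval over draws of the cells was -1.20 to 1.06, so neither the class mix nor handling in another run is excluded. The CD11b+ gate and its run cannot be told apart, and a biological difference between the gates may contribute as well.

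Granule transcripts stood at low TPM in cells of other classes, such as Camp in the Eryth cell. This was examined for abundant genes of the specific granule and late neutrophil lists, without primary granule genes. Abundant meant a mean of 1000 TPM or more in the Myelo cells of the gate. Over 40 pairs of a gate and such a gene, the level in cells outside the Myelo and Gran classes had a median of 0.071% of the level in Myelo cells, with quartiles a factor of 2.625 apart, as reads carried over within a run could give. The factor was 1.98 in Ly6g high, 34.1 in Ly6g low, with only 2 such cells, and 2.62 in CD11b+ cells. It depended on the minimum level, and was 48.3, 4.22 and 1.24 in Ly6g low cells at 300, 3000 and 10000 TPM. Over these minima it lay between 1.24 and 2.95 in Ly6g high and between 1.84 and 3.48 in CD11b+ cells. Prss34 was above 0 TPM in 4 of 40 other Ly6g low cells and 1 of 40 CD11b+ cells, a difference of 7.5 percentage points (Newcombe 95% interval -4.51 to 20.7) that decides nothing, and in 11 of 46 Ly6g high cells, a difference of 21.4 points (6.998 to 35.6), where it is not known whether both Ly6g gates were 1 library. Mcpt8 of the same cell was above 0 in 4 of 40 other Ly6g low, 8 of 46 Ly6g high and 6 of 40 CD11b+ cells. It reached 286 TPM in a CD11b+ cell of class Gran-2 (cell 4), but at most 6.02 TPM in Ly6g high and 2.4 TPM in the other Ly6g low cells. The CD11b+ gate is therefore no control for Mcpt8. Car1 of the Eryth cell was above 0 in 1 of 39 other CD11b+ cells. Carry-over stays open, and no biological explanation was tested.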
